A study of Mus musculus with 16 samples.

How the data were processed

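Gene expression was measured by RNA sequencing of cultured macrophages grown from the tibial bone marrow of C57BL/6 mice. Per the labels, the mice carried either 2 floxed Smad7 alleles (fl/fl, the control) or the floxed alleles together with a tamoxifen-inducible Cre recombinase driven by the CAGG promoter (KO). Mice aged 1 month received tamoxifen at 20 mg/kg for 5 days, and marrow was taken 2 weeks later. Cells were grown in medium with 15% serum and colony-stimulating factor 1 (CSF-1), at 12 ng/ml for 24 hours and then at 120 ng/ml for 48 hours. After about 12 hours without serum they were left untreated or given TGF-β1 at 10 ng/ml for 4 hours. Libraries were made from polyadenylated RNA and read as 150 bp pairs. The labels give 16 libraries, while the extraction protocol in the same labels speaks of 8 cDNA libraries, and nothing in the labels resolves that difference.

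Per the submitters' processing notes, TopHat2 2.0.9, HTSeq 0.6.1 and Cufflinks 2.1.1 were used with the builds mm10 and GRCm38.p6, named without roles or order. The counting options, including strand and the treatment of reads that map to several places, are not stated. The deposited count table holds raw read counts, as whole numbers, for 35275 Ensembl genes in 16 libraries. The deposited FPKM table holds FPKM, fragments scaled to gene length and library total, computed by the authors from those counts: 100% of the positive values equalled the count divided by the gene length and the library total, within 0.1%. Gene symbols and coordinates come from the deposited tables. Of the 35275 identifiers, 34490 were found in GENCODE M21, and 24932 had the same coordinates there.

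Totals of counts per library ran from 16865591 to 23741079, with a mean of 1.99e+07. Reads carry no molecular identifiers, so a floor of 3 counts, used where a gene had no count in a group, covers counting error only. Counts were scaled by trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, and filterByExpr on the 4 groups kept 13080 genes. Values are given as CPM (counts relative to the TMM-scaled total), as mean ± SD over the libraries of a group. Log2 fold changes are given ± SE. One edgeR quasi-likelihood model with robust estimation was fitted to the 16 libraries with a mean per group, and its F-tests were adjusted by the Benjamini-Hochberg method over the genes tested, at a threshold of 0.05. An adjusted p of a gene is edgeR's unless another tool is named. The comparisons were TGF-β1 against untreated in each genotype, KO against fl/fl in each treatment, and the difference between the 2 TGF-β1 responses as an interaction contrast.

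The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Smad7 and, per comparison, up to 8 genes with the highest and up to 8 with the lowest log2 fold change among characterised genes that pass the threshold, have an average log2 CPM of at least 1 and do not overlap between the groups. It also takes up to 2 rising and 2 falling members of each list, or the member with the lowest p. Some genes that the rule takes are not reported here. Where the text names a gene from outside the rule, it says that the gene was chosen after its values were seen.

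There were 34 lists covering TGF-β and BMP signalling, macrophage functions, metabolism, stress, proliferation and markers of the cell types that marrow culture can hold, and lists with at least 3 tested members were tested. The list test was camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. It was repeated with a correlation estimated per list. Counts of members past the threshold are also given adjusted over the list alone.

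The size of the response was compared across genes. The correlation of the 2 sets of log2 fold changes covers every tested gene, and the slope of KO on fl/fl covers the genes called for the average of both responses. Genes are not independent replicates, so no p is attached to these. A TGF-β1 score was computed for each library as the mean log2 CPM of 1095 genes that rose minus that of 1067 that fell in a fit of the 8 fl/fl libraries alone. The 8 KO libraries had no part in choosing those genes.

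Summed CPM of cell type lists, shares of mitochondrial, ribosomal protein and top 10 genes, Xist CPM, totals and detected genes were compared between groups by exact two-sided permutation tests, adjusted over 68 tests. With 4 against 4 libraries an exact test cannot go below p = 0.0286. Xist was high and Y-linked counts were between 0 and 2 in every library. No pair of libraries was identical.

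The library labelled KO untreated replicate 1 lay with the TGF-β1 libraries. It was kept where the labels place it, since the design was fixed, and each count was repeated without it. That repeat belongs to the leave-one-out alternatives for the genes and was added after seeing the data for the gene lists. Alternatives fixed in advance were size factors by relative log expression, DESeq2 1.42.0, no filter, a stricter filter, limma on log2 of FPKM with a pseudocount of 1, a minimum absolute log2 fold change of 1, fits of the compared libraries alone, a replicate block, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were fits without both libraries that stood apart, a term that sets replicate numbers 1 and 2 against 3 and 4, fits of the compared groups without KO untreated replicate 1, list tests with each library left out, and the spread against which a change in slope was judged. For that spread, the SD over all 16 pairs of KO libraries was 0.372, which pairs with KO untreated replicate 1 set, so the SD over the other 12 pairs, 0.0362, was used instead.

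Groups share replicate numbers 1 to 4. In fl/fl macrophages the untreated and treated library of the same number deviated from their group means together, with correlations across genes of 0.162, 0.173, 0.123 and 0.181. For KO these were 0.0754, 0.0816, 0.187 and 0.239. The KO untreated mean includes replicate 1, which lay with the treated libraries, so deviations in that group partly reflect that library. This limit holds for each correlation with the KO untreated group below, and not for those between the TGF-β1 groups. The match was not one to one, since fl/fl untreated replicate 1 correlated best with treated replicate 2 and untreated replicate 3 with treated replicate 4. Correlations were positive among numbers 1 and 2 and among 3 and 4 (0.0578 to 0.200 in fl/fl) and negative between them (-0.216 to -0.0435), in KO likewise. Between KO and fl/fl, libraries of the same number correlated negatively. For numbers 1 to 4 the values were -0.0849, -0.0619, -0.0773 and -0.175 untreated, and -0.131, -0.0219, -0.0285 and -0.0723 with TGF-β1. Equal numbers therefore do not mark a shift that both genotypes share. The labels give no pairing, so fits with replicates as blocks are an alternative only. Nothing in the labels says whether replicates are separate cultures or separate mice, so p-values measure only the spread between these samples.

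The tests were also checked on simulated data with 200 changed genes among 13080. The simulated libraries varied independently, with no library that stood apart and no structure of replicate numbers. With all 16 libraries, the interaction test recovered 29.9% of genes simulated at a 2-fold change and 72.7% at 4-fold. Leaving out KO untreated replicate 1 gave 46.3% and 71.2%. The corresponding shares for TGF-β1 in fl/fl were 56.7% and 86.4%. Reads, splicing and exon-level loss of Smad7 were not analysed here.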

Results

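Polyadenylated RNA was sequenced from 16 libraries of macrophages grown from mouse bone marrow, in 4 groups of 4. The groups were fl/fl macrophages, which keep Smad7, without and with TGF-β1 for 4 hours, and macrophages of mice in which Smad7 was deleted with tamoxifen (KO), again without and with TGF-β1. Smad7 is an inhibitory Smad, itself induced by TGF-β, that restrains signalling from TGF-β receptors. The comparisons ask which genes respond to TGF-β1 in each genotype and whether loss of Smad7 alters expression or that response. Total counts per library ran from 16865591 to 23741079, and 13080 genes were tested.

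Smad7 rose with TGF-β1 in both genotypes, and its level in KO macrophages was lower than in fl/fl in the fits that left out KO untreated replicate 1. Smad7 (ENSMUSG00000025880, chromosome 18, 75367529 to 75395935, mm10) was at 4.99 ± 0.895 CPM (SD, n = 4) in fl/fl untreated and 45.5 ± 9.20 CPM (SD, n = 4) in fl/fl TGF-β1 libraries. In KO libraries it was at 2.70 ± 2.14 CPM (SD, n = 4) without and 13.9 ± 4.36 CPM (SD, n = 4) with TGF-β1. The KO untreated libraries held 5.87, 1.28, 1.64 and 2.00 CPM for replicates 1 to 4, so replicate 1 lay within the fl/fl untreated range of 3.89 to 6.03 and the other 3 below it. With TGF-β1 each KO library, at 10.3 to 19.7 CPM, lay below each fl/fl library, at 37.3 to 58.3 CPM. Between genotypes Smad7 differed by -0.89 ± 0.37 log2 without TGF-β1 (edgeR adjusted p = 0.423) and by -1.72 ± 0.33 with it (edgeR adjusted p = 0.122), neither past the threshold. With KO untreated replicate 1 left out the values were -1.63 ± 0.27 (edgeR adjusted p = 0.0322) and -1.70 ± 0.21 (edgeR adjusted p = 8.9e-04), both past it. That library is in neither TGF-β1 group and bears on the second comparison through the shared fit. These are counts over the whole gene and do not show which exons were transcribed.

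**Figure D1:**
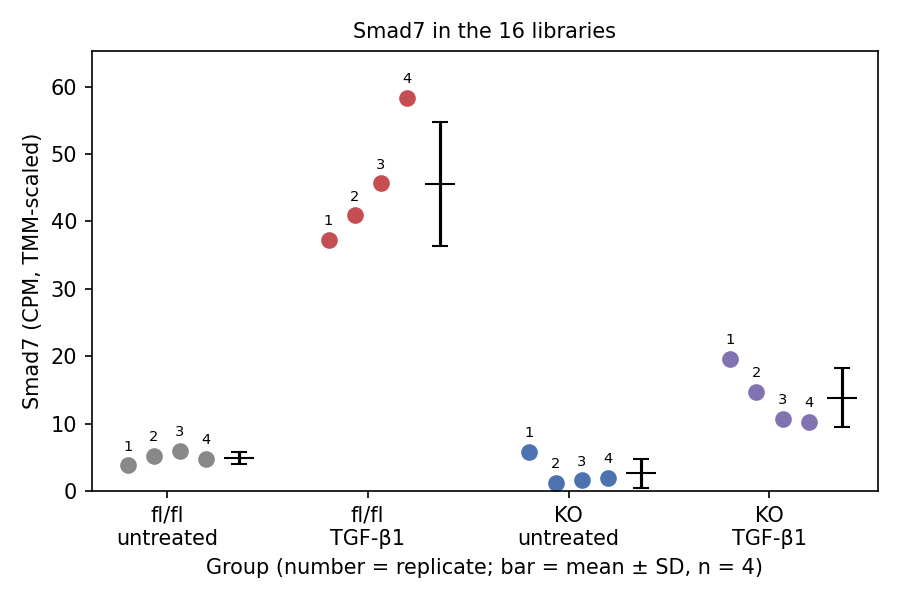
Smad7 expression in CPM (vertical axis) for each of the 16 libraries, grouped by genotype and treatment; points carry the replicate number and bars give the mean ± SD of 4 libraries. KO TGF-β1 libraries lie between 10.3 and 19.7 CPM, below the fl/fl TGF-β1 libraries at 37.3 to 58.3 CPM, and KO untreated replicate 1 lies at 5.87 CPM.

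The library labelled KO untreated replicate 1 lay with the treated libraries in its TGF-β1 score. That TGF-β1 score was 1.10, within the range of 1.09 to 1.56 of the 8 treated libraries, while the other 7 untreated libraries scored between -0.97 and -0.72. Pmepa1, a membrane protein induced by TGF-β, was at 320 CPM in this library, at 2.36 ± 0.578 CPM (SD, n = 3) in the other KO untreated libraries and at 324 ± 22.0 CPM (SD, n = 4) in KO TGF-β1 libraries. Skil, a transcriptional co-repressor of Smad proteins chosen after its values were seen, was at 655 CPM there, at 132 ± 23.4 CPM (SD, n = 3) in the others and at 662 ± 82.7 CPM (SD, n = 4) with TGF-β1. The endothelin receptor gene Ednrb, which fell with TGF-β1, was at 16.6 CPM in it against 186 ± 77.1 CPM (SD, n = 3) in the others. Smad7 lay apart from both, at 5.87 CPM in it against 1.28 to 2.00 CPM in the other 3 and 10.3 to 19.7 CPM in KO TGF-β1 libraries. The gene counts that use the KO untreated group are therefore given with and without this library. The model takes a shared estimate of the spread from all 16 libraries, so this library also bears on comparisons that do not use that group.

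**Figure D2:**
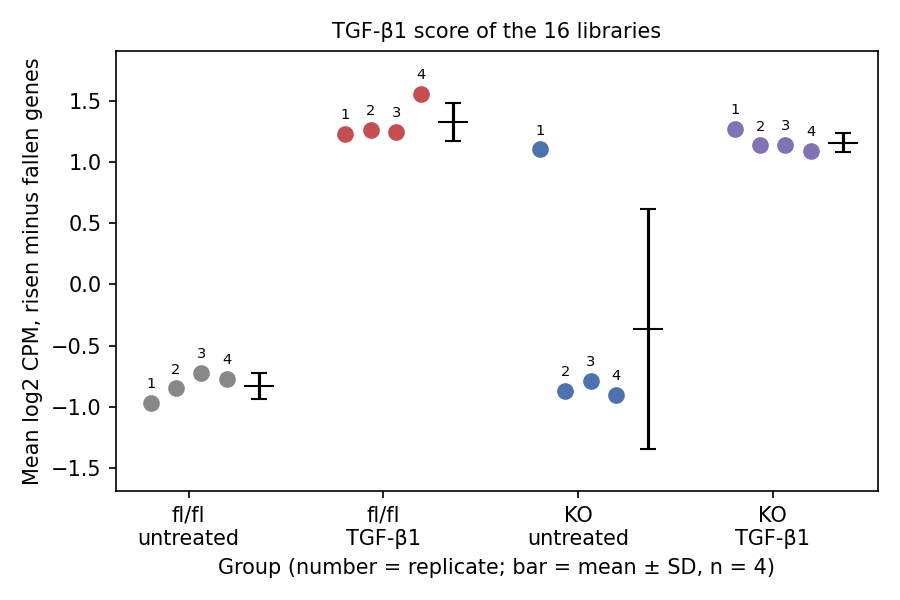
TGF-β1 score of each library (vertical axis, log2 CPM of 1095 genes that rose minus 1067 that fell in fl/fl macrophages); points carry the replicate number and bars give the mean ± SD of 4 libraries. KO untreated replicate 1 scores 1.10, among the treated libraries (1.09 to 1.56), and the other 7 untreated libraries score between -0.97 and -0.72.

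In fl/fl macrophages, TGF-β1 for 4 hours changed 2025 genes, of which 1030 were higher and 995 lower. Pmepa1 rose by 7.08 ± 1.58 log2, from 2.78 ± 0.311 to 376 ± 32.5 CPM (SD, n = 4). Among the characterised genes that did not overlap between groups and had an average log2 CPM of at least 1, other steep rises were those of the transcriptional repressor Hes1 (5.87 ± 1.29), the sulfotransferase Chst1 (5.61 ± 0.93), the inhibitor of DNA binding Id3 (5.50 ± 0.92), Tmeff1 (5.44 ± 1.12), Spsb1 (5.14 ± 1.17) and Prss46 (5.08 ± 1.19). Their edgeR adjusted p lay between 0.00135 and 0.00923. The steepest falls among such genes were those of Ednrb (-3.94 ± 0.57), Rnd3 (-3.78 ± 0.48), Sema6d (-3.71 ± 0.47), the aryl hydrocarbon receptor Ahr (-3.53 ± 0.42), Gprc5c (-3.43 ± 0.50), the iron exporter Slc40a1 (-3.31 ± 0.47), Pcdha10 (-3.19 ± 0.43) and the co-stimulatory receptor Cd28 (-3.08 ± 0.50). For these the edgeR adjusted p lay between 2.99e-04 and 0.00135. All of these genes kept their call when each library was left out in turn. A minimum change of 2-fold left 843 genes, 460 higher and 383 lower, and limma on log2 FPKM called 843 higher and 1345 lower. Without KO untreated replicate 1, TGF-β1 changed 2372 genes in fl/fl macrophages, 1165 higher and 1207 lower. That library is in neither group compared, but it enters the shared spread behind the SE and p-values given here.

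Targets of both branches of Smad signalling rose. Of 19 tested genes in the list of TGF-β/Smad2/3 targets, 13 were higher, 2 were lower and 4 did not pass (15 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.06e-08). Pmepa1, Spsb1 and Smad7 (3.18 ± 0.36) were among the risers, and the cell cycle inhibitors Cdkn2b (-1.82 ± 0.54) and Cdkn1a (-0.56 ± 0.17) were the 2 that fell. Of 8 tested BMP/Smad1/5 targets 5 were higher and none lower (7 higher adjusted over the list alone; camera adjusted p = 3.24e-06), with Id3 and the inhibitory Smad6 (4.70 ± 0.80) in front. Both lists missed the threshold with an estimated correlation, at an adjusted p = 0.286 each, and both passed it without KO untreated replicate 1, at an adjusted p = 0.00400 each. Among 21 ligands, receptors and transducers of TGF-β, 3 were higher and 5 lower (camera adjusted p = 0.377), including the receptor Tgfbr1 (1.69 ± 0.44) and Nrros (-1.53 ± 0.23), which holds latent TGF-β1 on myeloid cells.

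Of 15 tested microglia and resident macrophage genes, a list chosen for genes known to depend on TGF-β, 7 were higher, none lower and 8 did not pass (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.08e-04, and adjusted p = 0.286 with an estimated correlation). Cx3cr1, the fractalkine receptor, went from 54.1 ± 12.3 to 613 ± 98.0 CPM (SD, n = 4), and the secreted protein Olfml3 from 2.83 ± 0.587 to 42.3 ± 5.61 CPM (SD, n = 4). Growth and angiogenic factors had 5 of 12 members higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.00501, and adjusted p = 0.286 with an estimated correlation), with Pdgfa at 3.60 ± 0.70 log2. In the glycolysis list 5 of 18 were higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0470, and adjusted p = 0.511 with an estimated correlation), led by the hexokinase Hk2 (edgeR adjusted p = 0.00190). The glycolysis call ended with replicates as blocks (adjusted p = 0.0683) and without fl/fl untreated replicate 1 (0.122) or 2 (0.0602), fl/fl TGF-β1 replicate 1 (0.0725) or 4 (0.231), or KO TGF-β1 replicate 2 (0.0507).

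Type I interferon-stimulated genes, NF-κB feedback genes and innate sensors were lower with TGF-β1, while chemokines split. All 10 of the 26 type I interferon-stimulated genes that passed the threshold were lower (19 lower adjusted over the list alone; camera adjusted p = 3.24e-06, and adjusted p = 0.486 with an estimated correlation). The antiviral Mx1 went from 114 ± 40.5 to 23.0 ± 8.19 CPM (SD, n = 4) and Rsad2 from 277 ± 84.4 to 58.8 ± 21.4 CPM (SD, n = 4). Of 18 NF-κB feedback genes 10 were lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.47e-04, and adjusted p = 0.396 with an estimated correlation), with Tnip3 at -2.03 ± 0.33 and Cd40 at -1.37 ± 0.31. Of 20 Toll-like receptors and innate sensors 10 were lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.43e-05, and adjusted p = 0.286 with an estimated correlation), among them Clec7a, the receptor for fungal glucans (-2.06 ± 0.45). Of the chemokines 8 of 16 were lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p = 0.00501). Cxcl10 (-2.40 ± 0.59) and Ccl4 (-1.84 ± 0.46) fell, while Cxcl14 (2.29 ± 0.51) and Cxcl16 (1.31 ± 0.22) rose. The chemokine call was lost with an estimated correlation (adjusted p = 0.286) and held in that test without KO untreated replicate 1 (adjusted p = 0.0251).

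Cholesterol synthesis and p53 target genes were lower as well. Of 18 cholesterol synthesis genes 10 were lower and none higher (12 lower adjusted over the list alone; camera adjusted p = 3.24e-06, and adjusted p = 0.358 with an estimated correlation), including the isomerase Idi1 (-0.84 ± 0.20). Of 16 p53 targets 6 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.00753, and adjusted p = 0.286 with an estimated correlation). Pmaip1 (-2.22 ± 0.36) and the death receptor Fas (-1.40 ± 0.30) fell, and Mdm2 (0.41 ± 0.11) rose.

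In KO macrophages TGF-β1 changed 676 genes, 287 higher and 389 lower, and without KO untreated replicate 1 it changed 1989, with 1089 higher and 900 lower. Of the 676 genes, 675 were also called without that library. Among characterised genes that did not overlap between groups and had an average log2 CPM of at least 1, Ednrb went from 144 ± 106 to 10.8 ± 3.50 CPM (SD, n = 4), by -3.73 ± 0.56 log2, and B3gnt5 (-3.31 ± 0.82), Rnd3 (-3.19 ± 0.46), Gprc5c (-3.05 ± 0.49), Pcdha10 (-2.97 ± 0.44), Slc40a1 (-2.90 ± 0.46), Cytip (-2.78 ± 0.59) and Ahr (-2.57 ± 0.39) followed. The steepest rises among such genes were those of Zfp618 (2.58 ± 0.61), the serotonin receptor Htr2b (2.39 ± 0.58), Smad7 (2.36 ± 0.37), Dlx2 (2.23 ± 0.62), the lectin Cd207 (2.15 ± 0.55), Myh15 (2.04 ± 0.50), Notch4 (1.89 ± 0.50) and Cdk5r1 (1.84 ± 0.46). The edgeR adjusted p of these 16 genes lay between 0.00689 and 0.0451. With KO untreated replicate 1 left out the rises were 4.63 log2 for Zfp618, 3.96 for Htr2b, 3.11 for Smad7, 2.98 for Dlx2, 2.98 for Cd207, 2.80 for Myh15, 3.10 for Notch4 and 2.98 for Cdk5r1, and the falls ran from -4.07 for Ednrb to -2.86 for Ahr. Pmepa1, by contrast, did not pass (1.98 ± 1.21, edgeR adjusted p = 0.468), and without KO untreated replicate 1 it rose by 7.12 ± 0.17 (edgeR adjusted p = 1.33e-14). The rule counted that library as untreated, so it passed over genes in which the library lay at treated levels. The rises named here are therefore not the steepest in KO macrophages when it is left out, as Pmepa1 shows.

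The KO count of 676 depended on the library left out, and was 1989 without KO untreated replicate 1. With that library kept, the count was 149, 109 and 93 without KO untreated replicates 2, 3 and 4, and 248, 195, 94 and 127 without KO TGF-β1 replicates 1 to 4. Without fl/fl untreated replicates 2 and 3 it was 409 and 422. A fit of the 8 KO libraries alone called 0 genes by edgeR, with 1916 at an unadjusted p under 0.05, against 1839 called when KO untreated replicate 1 was left out of that fit. On all 16 libraries DESeq2 called 1093, a minimum change of 2-fold left 278 (80 higher and 198 lower), no filter gave 446, and limma on log2 FPKM called 463 higher and 344 lower. Of the 16 genes named, Smad7, Ednrb, Rnd3, Gprc5c, Pcdha10, Slc40a1 and Ahr kept their call whichever library was left out. The other 9 lost it in some of those fits, at an edgeR adjusted p of at most 0.149, which B3gnt5 reached without KO untreated replicate 2. Leaving out that replicate took B3gnt5 to -1.78 log2 and Cytip to -1.45 (edgeR adjusted p = 0.0215).

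In KO macrophages 11 gene lists were called by camera, and none of them with an estimated correlation (lowest adjusted p = 0.148, for BMP targets). TGF-β/Smad2/3 targets had 5 of 19 higher and 1 lower (12 and 3 adjusted over the list alone; camera adjusted p = 2.00e-10), and 15 higher and 3 lower without KO untreated replicate 1. BMP/Smad1/5 targets had 2 of 8 higher (7 adjusted over the list alone; camera adjusted p = 9.91e-08), with Id1 (2.47 ± 0.63) and Id2 (1.81 ± 0.30), and 7 higher without that library. Microglia and resident macrophage genes had 2 of 15 higher (6 adjusted over the list alone; camera adjusted p = 3.16e-06), and 7 without it. Falling members numbered 5 of 26 for type I interferon (17 adjusted over the list alone; camera adjusted p = 2.82e-07), 6 of 18 for NF-κB feedback (12; 2.34e-06), 7 of 20 for innate sensors (10; 2.26e-04) and 2 of 16 for p53 targets (4 lower and 1 higher; 0.00362). Chemokines had 7 of 16 lower and 1 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.00120), growth factors 1 lower and 1 higher of 12 (1 and 4; 0.00216), MHC class II genes 2 of 12 lower (5; 0.0143) and LXR targets 1 of 13 higher (3 higher and 1 lower; 0.0330). Leaving out that library, lower members numbered 20 for type I interferon, 14 for NF-κB feedback, 11 for innate sensors (1 higher), 4 for p53 targets (1 higher), 8 for chemokines (2 higher) and 5 for MHC class II genes. In the same fit growth factors had 5 higher and 1 lower, and LXR targets 4 higher and 1 lower.

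Among these KO members, Mx1 fell by 2.31 on the log2 scale, Cxcl10 by 2.30, Nod1, a sensor of bacterial peptidoglycan, by 1.73, and Pmaip1 by 2.12. Without KO untreated replicate 1 the test with an estimated correlation called TGF-β and BMP targets (adjusted p = 0.00298 each), chemokines (0.00575) and p53 targets (0.0381). The MHC class II call ended without KO TGF-β1 replicate 3 (camera adjusted p = 0.0530), and the LXR call without KO untreated replicate 3 (0.0780) or 4 (0.0728) or KO TGF-β1 replicate 2 (0.0749). Glycolysis genes had no member past the threshold in KO macrophages by edgeR (2 higher adjusted over the list alone; camera adjusted p = 0.509). Cholesterol synthesis genes had none either (none adjusted over the list alone; camera adjusted p = 0.0712), and their call was made without KO untreated replicate 1 (0.0251) or 2 (0.0354) or KO TGF-β1 replicate 2 (0.0127) or 4 (0.0365), and with replicates as blocks (0.0258).

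Genes called in both genotypes changed in the same direction, and no gene was called as differing between them by edgeR. Of 287 genes higher in KO macrophages 274 were also higher in fl/fl, where independent lists would share 22.6, and of 389 lower genes 354 were shared, against 29.6. No gene was called in opposite directions. Across the 13080 tested genes, which are not independent replicates, the log2 fold changes correlated with a Pearson coefficient of 0.733 and a Spearman coefficient of 0.601. Over 2801 genes called for the average response, a choice that favours genes moving alike, the slope of KO on fl/fl was 0.641. Leaving out KO untreated replicate 1, the slope was 0.960 over 3344 genes, and the share of genes with the larger change in KO went from 17.7% to 50.8%.

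The interaction contrast itself called 0 genes by edgeR with all libraries, with 275 genes at an unadjusted p under 0.05 where 654 were due by chance, and a smallest adjusted p of 0.993. Without KO untreated replicate 1 it also called 0, with 256 at an unadjusted p under 0.05. Both numbers lie below the chance number, so the test may have been conservative on these libraries, and the cause was not tested. A count of 0 is therefore little evidence of equal responses. Limma on log2 FPKM called 0 and DESeq2 called 1, Bnc2, chosen after its values were seen. Bnc2 was at 0 CPM in KO untreated replicates 2 to 4 and at 3.63 CPM in replicate 1. On simulated data the same contrast recovered 4.48% of genes with a 1.5-fold difference in response, 29.9% at 2-fold and 72.7% at 4-fold. Leaving out KO untreated replicate 1 put these shares at 4.48%, 46.3% and 71.2%. With and without that library, most simulated differences of 2-fold or less were missed. The simulation held no library that stood apart and no structure of replicate numbers, so its shares need not carry over to the real libraries. For Smad7 the difference in response was -0.83 ± 0.50 log2 (edgeR adjusted p = 0.993) with all libraries and -0.07 ± 0.36 without KO untreated replicate 1 (edgeR adjusted p = 0.995). Among lists, cholesterol synthesis genes had a less negative response in KO (median 0.27 log2; camera adjusted p = 1.71e-06, and adjusted p = 0.813 with an estimated correlation), with 0 members past the threshold by edgeR over all genes and 0 adjusted over the list alone. That list kept its call without KO untreated replicate 1 (camera adjusted p = 0.00149). Type I interferon genes were called in that fit and not with all libraries, with a more negative response in KO (median -0.16 log2; camera adjusted p = 0.00838, and adjusted p = 0.834 with an estimated correlation). Other lists missed the threshold with all libraries and passed camera in some fits that left a library out. TGF-β/Smad2/3 targets (0.0845) passed without KO untreated replicate 2 (7.16e-04), 3 (0.0310) or 4 (0.0359). Of the 16 fits that left a library out only these 3 called that list. Each kept KO untreated replicate 1, which lay with the treated libraries, in a smaller KO untreated group. Innate sensors (0.0845) passed with replicates as blocks (0.0214), without KO untreated replicate 2 (0.0219), 3 (0.0338) or 4 (0.0199), fl/fl untreated replicate 3 (0.0263) or 4 (0.0410), and KO (0.0170) or fl/fl (0.0323) TGF-β1 replicate 1. Glycolysis genes (0.0845) passed without KO untreated replicate 3 (0.0310), fl/fl untreated replicate 4 (0.0243), KO TGF-β1 replicate 2 (0.0438) or 4 (0.0421), or fl/fl TGF-β1 replicate 3 (0.0221). Microglia (0.0428) and stress response genes (0.0381) passed without KO untreated replicate 2, in a fit that also kept KO untreated replicate 1.

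**Figure D3:**
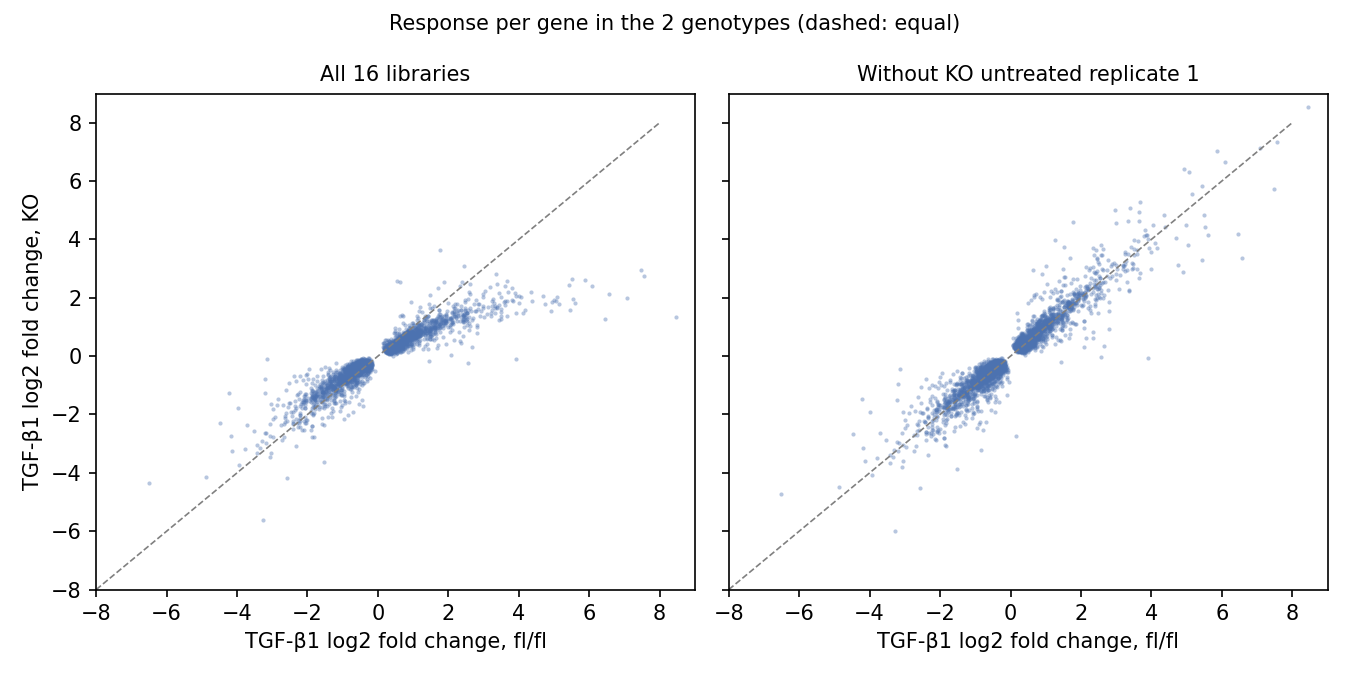
Log2 fold change with TGF-β1 in KO (vertical axis) against fl/fl macrophages (horizontal axis) for the genes called for the average response; each point is a gene, and the dashed line marks equal change. With all 16 libraries the slope over 2801 genes is 0.641, and without KO untreated replicate 1 the slope over 3344 genes is 0.960.

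Few genes passed the threshold between KO and fl/fl macrophages without TGF-β1: 6 passed, 1 higher and 5 lower. At an unadjusted p under 0.05 edgeR gave 1421 genes, and 1566 without KO untreated replicate 1, where 654 were due by chance. Few calls therefore do not show that the genotypes were alike. Genes move together within libraries, so the excess is no count of differing genes either. Adam19, a membrane-bound metalloproteinase (ENSMUSG00000011256, chromosome 11, 46055992 to 46147343), was at 6.98 ± 3.84 CPM (SD, n = 4) in KO and 30.4 ± 5.53 CPM (SD, n = 4) in fl/fl libraries, a difference of -2.12 ± 0.29 log2 (edgeR adjusted p = 0.00305). Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA (ENSMUSG00000027487, chromosome 2, 154335380 to 154373010), was at 14.8 ± 1.68 against 6.87 ± 0.650 CPM (SD, n = 4), higher by 1.11 ± 0.17 (edgeR adjusted p = 0.0166). The pseudogene Rps3a2 was lower, with a difference of -2.29 ± 0.30 (edgeR adjusted p = 0.00235). The remaining 3, chosen after their values were seen, were the pseudogenes Gm11868 (-6.77 ± 0.48) and Gm3608 (-3.98 ± 0.20) and the histone gene Hist1h2al. Hist1h2al had 0 counts in KO and 119 in fl/fl libraries, at least 41.0-fold lower with a floor of 3 counts over the group. Pseudogenes and histone genes have near-identical copies, and how the counting shared reads among them is not stated, so their values are uncertain.

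Without KO untreated replicate 1, 13 genes differed, 4 higher and 9 lower, and all 6 were among them. The count was 10 without KO TGF-β1 replicate 1 and 10 without fl/fl TGF-β1 replicate 4, and DESeq2 called 61. In a fit of the untreated libraries alone, Adam19 (edgeR adjusted p = 0.290) and Rps3a2 (0.0878) lost their calls. With KO untreated replicate 1 left out of that fit, both stayed beyond the threshold (0.112 and 0.0680). Cdk5rap1 lost its call without KO untreated replicate 2 (edgeR adjusted p = 0.0715) or 4 (0.0536) and without fl/fl untreated replicates 1 to 4 (0.0877, 0.112, 0.0587 and 0.0727). Hist1h2al lost its call in the same 6 fits (edgeR adjusted p = 0.0575 and 0.0536 for the KO libraries, and 0.0832, 0.0573, 0.0587 and 0.0706 for the fl/fl ones). Cholesterol synthesis genes were lower in KO as a group (median -0.41 log2; camera adjusted p = 1.10e-11), with 0 of 18 past the threshold by edgeR over all genes and 11 lower adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.926) and held in camera whichever library was left out (highest adjusted p = 6.17e-07). TGF-β1 targets as a list were not called (median 0.45 log2; camera adjusted p = 0.160) but passed without KO untreated replicate 2 (7.31e-04). That fit kept KO untreated replicate 1. Leaving out replicate 1 instead took the median of these targets to 0.02 log2 (camera adjusted p = 0.331, towards lower). Without KO untreated replicate 1, 3 further lists were called: type I interferon genes higher (3.64e-05), inflammatory mediators higher (0.00489), and ligands, receptors and transducers of TGF-β lower (0.0264). Only the first needed that library left out, since the mediators also passed without fl/fl untreated replicate 1 (0.0424), and the TGF-β ligand list without fl/fl untreated replicate 3 (0.0461) or 4 (0.0436). In the fit without KO untreated replicate 1 and with an estimated correlation none of the 3 held (lowest adjusted p = 0.487).

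With TGF-β1, 5 genes passed between KO and fl/fl macrophages, 1 higher and 4 lower. At an unadjusted p under 0.05 edgeR gave 734 genes, where 654 were due by chance. Esr1, the estrogen receptor gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), was at 10.8 ± 2.24 against 4.65 ± 0.934 CPM (SD, n = 4), higher by 1.21 ± 0.20 log2 (edgeR adjusted p = 0.0291). Without TGF-β1 it was at 14.5 ± 3.03 against 7.33 ± 1.23 CPM (SD, n = 4), a difference of 0.99 ± 0.20 that did not pass (edgeR adjusted p = 0.0884), and that passed without KO untreated replicate 1 (edgeR adjusted p = 0.0471). Rps3a2 was lower, with a difference of -2.37 ± 0.30 (edgeR adjusted p = 0.00167), and Gm11868 (-5.78 ± 0.45) and Gm3608 (-3.68 ± 0.20) were lower again. Hist1h2al had 0 counts against 197. With the same floor it was at least 40.6-fold lower without fl/fl TGF-β1 replicate 4, which alone was at 5.68 CPM and raised that bound to 68.1-fold. All 4 lower genes were among the 5 lower without TGF-β1. Adam19 was at -1.58 ± 0.29 (edgeR adjusted p = 0.0698), and passed without KO untreated replicate 1 (edgeR adjusted p = 0.00838).

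Without that library 8 genes passed, 1 higher and 7 lower, Smad7 and Adam19 among them, and DESeq2 called 23 on all 16 libraries. Esr1 lost its call without KO TGF-β1 replicates 2, 3 and 4 (edgeR adjusted p = 0.173, 0.0617 and 0.0748), without fl/fl TGF-β1 replicates 1, 2 and 4 (0.158, 0.165 and 0.0910) and without fl/fl untreated replicate 4 (0.0542). Glycolysis genes were lower in KO as a group (median -0.14 log2; camera adjusted p = 0.00687), with 0 of 18 past the threshold by edgeR over all genes and 0 adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.991) and without KO TGF-β1 replicate 1 (camera adjusted p = 0.194) or fl/fl TGF-β1 replicate 4 (0.224). Phagocytosis genes lay just beyond the threshold (median -0.11 log2; camera adjusted p = 0.0506), and passed in 10 of the 16 fits that left a library out, at 0.0196 without KO untreated replicate 1. Cholesterol synthesis genes were not called (median -0.08 log2; camera adjusted p = 0.345) but passed without KO TGF-β1 replicate 2 (0.0390) or fl/fl TGF-β1 replicate 3 (0.00579).

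Several sums of cell type markers lay apart between treated and untreated libraries. With 4 against 4 libraries an exact permutation p cannot go below 0.0286, so over 68 tests adjustment could hardly be passed (lowest adjusted p = 0.194) and says little about a difference. Summed monocyte markers in fl/fl macrophages with and without TGF-β1 were at 843 ± 64.7 against 385 ± 64.6 CPM (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194), a sum that holds Cx3cr1. Summed B cell markers were at 100.1 ± 13.2 against 185 ± 21.5 CPM (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194). For endothelial markers the sums were 133 ± 19.5 and 80.2 ± 5.57 CPM (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194). Most of the endothelial sum with TGF-β1 was Vwf, at 98.0 to 137 CPM in the fl/fl TGF-β1 libraries. Dendritic cell markers summed to 475 ± 93.2 and 338 ± 25.0 CPM (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194), and T and NK cell markers to 1.59 ± 0.201 and 0.506 ± 0.263 CPM with the same p. Of the B cell and the T and NK cell markers only 2 and 1 had enough counts to be tested as genes, so those sums rest on few genes. In KO macrophages the sums with and without TGF-β1 were 734 ± 76.5 and 375 ± 157 CPM for monocyte, 92.1 ± 13.5 and 175 ± 38.9 CPM for B cell, 460 ± 47.9 and 379 ± 17.5 CPM for dendritic and 113 ± 15.8 and 68.4 ± 20.6 CPM for endothelial markers (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194 for each). The 10 most abundant genes took 9.98 ± 0.289% of counts in KO TGF-β1 and 11.6 ± 0.728% in fl/fl TGF-β1 libraries (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.194). Replicate 4 of fl/fl TGF-β1 had 0.575% mitochondrial counts and 14915 detected genes, against 1.54% to 1.83% and 16688 to 17017 in its group, and without it TGF-β1 changed 1720 genes in fl/fl macrophages.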

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

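The tests on KO untreated replicate 1 and on the genes that differ between genotypes were chosen only after those results were seen, while those on fl/fl TGF-β1 replicate 4 and the splits of the libraries were written down first, except the split without KO untreated replicate 1. A library far from the other 3 of its group was found in 51 of 344 groups of values, and 32 of the 51 were in KO untreated replicate 1 and 9 in fl/fl TGF-β1 replicate 4. For independent values chance gives about 1 in 20 groups (17.2). Most values here were CPM of genes named in the text, many of them chosen for their TGF-β1 response. Such values move together within a library, so 17.2 is no fair expectation and the 32 are not separate results.

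KO untreated replicate 1 lay with the treated libraries, at a TGF-β1 score of 1.10 where the other KO untreated libraries scored -0.90 to -0.79. An fl/fl mouse as its source is argued against by 2 of 2 pseudogenes below every fl/fl library, Gm11868 at 0 CPM against 3.28 to 11.8 and Gm3608 at 3.49 CPM against 28.0 to 65.9. These 2 were chosen with this library counted as KO. Without it they also parted the untreated genotypes, by -6.39 log2 (edgeR adjusted p = 8.95e-07) and -3.94 log2 (edgeR adjusted p = 1.52e-08). The other KO libraries held 0.0538 to 0.221 CPM of Gm11868 and 3.24 to 4.73 CPM of Gm3608. Loss of Smad7 as such is argued against by the other 3 KO untreated libraries, whose mean score was lower than the highest fl/fl untreated score (a difference of -0.13). Exposure to TGF-β1, or a treated KO library under this label, may account for the score of 1.10, in the treated range of 1.09 to 1.56, but Smad7 at 5.87 CPM was below the 10.3 to 19.7 CPM of KO TGF-β1 libraries. No treated library lay in the untreated range (0 of 8), so a swap within these 16 libraries is not seen, while a single wrong label, or an exposure that differed from that of the treated libraries, stays open.

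In this library the values apart from the other 3 were higher for Smad7 (5.87 CPM), Pmepa1 (320), Hes1 (5.68), Chst1 (6.25), Id3 (62.5), Tmeff1 (21.5), Spsb1 (112), Prss46 (4.11), Smad6 (54.6), Olfml3 (59.7), Cx3cr1 (369), Cxcl14 (58.0), Cxcl16 (302), Pdgfa (134), Hk2 (229), Itgav (404), Mmp2 (20.1) and Cebpa (747). They were also higher for Zfp618 (2.01 CPM), Htr2b (17.8), Notch4 (34.5), Cdk5r1 (13.2), Id2 (56.1), Skil (655), Bnc2 (3.63) and the monocyte sum (610), and lower for Gprc5c (10.3 CPM), Rsad2 (30.6), Pmaip1 (3.77), Cd163 (5.11) and Mmp13 (5.78).

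Of the 7 genes called between the genotypes 3 are pseudogenes, 42.9% against 2.73% of the genes tested (one-sided Fisher's exact p = 6.5e-04). The test was chosen after these pseudogenes were seen, so it describes them and adds no separate support. Reads of near-identical copies, or a variant of the mouse lines, may underlie part of these calls. Esr1 was higher in all 8 KO libraries than in the highest of the 8 fl/fl libraries, and the inducible Cre is fused to an estrogen receptor domain. Reads of that transgene counted as Esr1 are a candidate explanation, and a rise of Esr1 itself was not excluded.

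Replicate 4 of fl/fl TGF-β1 stood apart in its score (1.56), Xist (332 CPM), detected genes (14915), the neutrophil sum (155 CPM), Gprc5c (13.8 CPM), Cd28 (10.999), Ccl4 (10.6), Gm11868 (3.28) and Hist1h2al (5.68). A larger TGF-β1 response over all tested genes is argued against by a Spearman correlation of 0.00255 between its deviations from its group and the KO response. Its score of 1.56, against 1.23 to 1.26 in the rest of its group, points the other way for the genes in the score. Those genes were chosen with this library among the treated ones, so a larger response of them is neither shown nor excluded. Its deviations correlated with GC content at 0.516, where the largest correlation with GC or length in the other 15 libraries was 0.411, so a GC bias may contribute. Cells of another type stayed undecided, since the highest deviation of a marker list was 0.87 log2 over 3 stromal genes and other libraries ran from -2.23 to 1.25.

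Libraries apart from their groups in other values were fl/fl TGF-β1 replicate 3 in the endothelial sum (104 CPM) and Vwf (98.0 CPM), fl/fl TGF-β1 replicate 1 in Rsad2 (90.7 CPM), fl/fl untreated replicate 4 in Mmp13 (31.6 CPM) and replicate 1 in Hist1h2al (1.97 CPM). KO TGF-β1 replicate 4 was apart in Mmp13 (9.98 CPM), and KO untreated replicate 2 in mitochondrial counts (2.71%), ribosomal protein counts (4.25%), B3gnt5 (19.8 CPM) and Cytip (313 CPM). The difference in response of cholesterol synthesis genes between genotypes passed camera (adjusted p = 1.71e-06) and not the test with an estimated correlation (adjusted p = 0.813).

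Splits of the compared libraries were counted in fits of those libraries alone. For TGF-β1 in fl/fl macrophages 1 of 35 splits, the real one, gave as many genes (2162, highest other 7). This share is under 0.05 and the lowest that 35 splits allow. The other splits mix treated with untreated libraries, so the share argues against chance without excluding it. In KO macrophages the real split gave 0 genes by edgeR and the highest other 18, so 35 of 35 gave as many. Any split must do so against a count of 0, so this says nothing about chance. Without KO untreated replicate 1 it was 1 of 35 (1839, highest other 6), but that library was left out after its score was seen, so this count does not test chance. Between genotypes 2 of 35 splits gave as many without TGF-β1 (4, highest other 13) and 2 of 35 with it (6, highest other 15), so for these counts chance is not excluded. The 4 lower genes with TGF-β1 were all among those lower without it, where independent lists would share 0.00153, but libraries of the same number and genotype deviate together, so this is no independent repeat. In both comparisons, the split that gave more set KO 1 and 2 with fl/fl 3 and 4 against the rest, which points to a structure of the samples. With a term for replicate numbers 1 and 2 against 3 and 4 the counts were 8 and 6. That term sets KO 1 and 2 with fl/fl 1 and 2, so these counts do not bear on that structure. For the difference in response 50 of 50 splits, the real one among them, gave as many as the real one (0 by edgeR, highest other 0). A real count of 0 made that outcome certain, so it does not test chance either.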

How the results depend on the processing

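Fits without both libraries that stood apart, of 2 groups without KO untreated replicate 1, with a term for replicate numbers, and list tests with a library left out were chosen only after the data were seen. No named gene that passed the threshold in the main fit or in an alternative changed direction between the 2. Genes that passed in neither were not counted for this. Where a value moved, the cause was not tested. The balance of higher and lower genes did turn: for TGF-β1 in KO it was 287 to 389, but 1089 to 900 without KO untreated replicate 1, 463 to 344 by limma and 513 to 481 with replicates as blocks, and in fl/fl it was 1030 to 995, but 843 to 1345 by limma and 1010 to 1184 with blocks. Genes changed by TGF-β1 in fl/fl macrophages numbered 1379 to 2372 with a library left out, 843 with a 2-fold minimum and 1701 to 2439 otherwise, against 2025. In KO macrophages, against 676, they numbered 93 to 1989 with a library left out, 1093 by DESeq2, 446 without a filter, 278 with a 2-fold minimum, 0 by edgeR in the 8 libraries alone (1916 at an unadjusted p under 0.05), 1839 there without KO untreated replicate 1 and 2501 without both libraries. Between genotypes without TGF-β1, against 6, the counts were 4 (without KO untreated replicate 4) to 13, 61 by DESeq2, 10 without a filter and 17 without both. With TGF-β1, against 5, they were 4 to 8, 23 by DESeq2 and 13 without both. The interaction count was 0 by edgeR and limma and 1 by DESeq2. The slope was 0.567 (without KO untreated replicate 2) to 0.960, and 0.977 without both, against 0.641.

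Lists called with an estimated correlation numbered 0 in each of the 5 comparisons. By fry they were 0 for both genotype comparisons and the difference in response. With a library left out they were 10 to 14 and 10 to 13 for TGF-β1 in fl/fl and KO, 1 to 4 and 0 to 2 between genotypes without and with TGF-β1, and 1 to 5 for the difference in response. Without both libraries the last 3 were 4, 0 and 3, and with replicates as blocks 2 lists were called between genotypes with TGF-β1 and 2 for the difference in response. With blocks 994 genes were called for TGF-β1 in KO, of which 598 were shared with the 676, and 4 in each genotype comparison, all lower. Of these, 4 were shared with the 6 without TGF-β1, where Cdk5rap1 and Hist1h2al lost their calls (both adjusted p = 0.0746), and 3 with the 5 with it, where Esr1 (0.101) and Hist1h2al (0.0716) lost theirs. For the genotype comparisons the block ties KO and fl/fl libraries of the same number, which correlated negatively across genes (-0.175 to -0.0219), so those losses rest on a doubtful pairing. The block moved no other gene count by more than 1.5 times. Named genes are counted here once per comparison that takes them, and fits of 2 groups alone do not cover the difference in response. Calls were lost by 63 in those fits, 40 with a 2-fold minimum, 25 without a filter, 16 by limma and 10 by DESeq2. With a library left out, the highest numbers were 45 and 44 without KO TGF-β1 replicates 3 and 4, and 43 without KO untreated replicate 4. Without KO untreated replicate 1 the number was 0, and 10 calls were gained. DESeq2 also gained 10. On simulated data most differences in response of 2-fold or less were missed, and what set that limit was not tested.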

Other observations

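The list tests on all 16 libraries in this part were fixed in advance, though no prediction was written for any list. Fits that left a library out of the list tests were chosen only after the data were seen. Macrophage core genes that rose with TGF-β1 in fl/fl macrophages included the transcription factor Cebpa (2.15 ± 0.35 log2), with 2 of 13 higher and none lower (camera adjusted p = 0.279). Alternative activation genes split, with the transglutaminase Tgm2 at 2.62 ± 0.49 and the haemoglobin scavenger receptor Cd163 at -2.60 ± 0.37 (3 higher and 5 lower of 15; camera adjusted p = 0.377). The gelatinase Mmp2 rose by 4.17 ± 0.82 and the collagenase Mmp13 fell by 1.64 on the log2 scale (3 higher and 1 lower of 17 proteases; camera adjusted p = 0.377). The integrin Itgav, at 2.17 ± 0.39, was among 2 of 13 matrix genes higher (camera adjusted p = 0.279) and 8 of 23 phagocytosis genes higher, with 2 lower (camera adjusted p = 0.0834, and 0.0315 without KO untreated replicate 1). Among 13 LXR targets the cholesterol exporter Abca1 was at 0.72 ± 0.18 and the lipase Lpl at -1.01 ± 0.24 (2 higher and 1 lower; camera adjusted p = 0.0609).

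Other lists were not called for TGF-β1 in fl/fl macrophages with all 16 libraries. Members past the threshold were 1 higher and 1 lower of 8 inflammatory mediators (camera adjusted p = 0.279), 3 lower of 12 MHC class II genes (0.0604), 1 higher of 23 proliferation genes (0.627), 3 lower of 14 stress response genes (0.104) and 2 lower of 10 osteoclast genes (0.627). They were 4 higher and 2 lower of 20 immediate-early genes (0.639). In the osteoclast and immediate-early lists the median (0.10 and -0.15 log2) and the test differed in sign. For markers of other cells they were 1 higher of 10 monocyte (0.643), 1 of 9 neutrophil (0.401), 1 of 8 dendritic (0.651) and 1 of 5 endothelial genes (0.0501, with Vwf at 0.88 ± 0.23), and none of 4 megakaryocyte (0.359) and 3 stromal genes (0.396). The MHC class II list passed without fl/fl TGF-β1 replicate 4 (0.0146), KO untreated replicate 1 (0.0340) or 2 (0.0297), or fl/fl untreated replicate 3 (0.0474) or 4 (0.0247). The LXR list passed without KO untreated replicate 2 (0.0483) or fl/fl TGF-β1 replicate 3 (0.0401), and the stress response list without fl/fl untreated replicate 1 (0.0485) or fl/fl TGF-β1 replicate 4 (0.0417). The endothelial list passed with replicates as blocks (0.0341) and in 8 of 16 fits that left a library out: KO untreated replicates 2, 3 and 4 (0.0252, 0.0450 and 0.0369), fl/fl untreated replicates 1, 2 and 4 (0.0228, 0.0259 and 0.0415), KO TGF-β1 replicate 4 (0.0447) and fl/fl TGF-β1 replicate 3 (0.0311). B cell, T and NK cell, erythroid and mast cell lists had 2, 1, 2 and 1 tested members and no list test.

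In KO macrophages inflammatory mediators had no member past the threshold by edgeR (2 lower adjusted over the list alone; camera adjusted p = 0.0523). The list passed with replicates as blocks (0.0130) and in 9 of 16 fits that left a library out, with the lowest adjusted p without KO TGF-β1 replicate 3 (0.0198) and 0.0251 without KO untreated replicate 1. Replicate 1 of KO TGF-β1 libraries had the highest Smad7 of its group, at 19.7 CPM.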
